A study of Mus musculus with 4 samples.

How the data were processed

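Gene expression was measured by RNA sequencing in LSK cells, the lineage-negative, Kit-positive and Sca-1-positive fraction of mouse bone marrow that holds stem cells and early multipotent progenitors. The cells were sorted from Zfp521 knockout mice and from control littermates. Zfp521 encodes a zinc finger transcription cofactor. Per the labels' protocols, libraries were made from 20 ng of total RNA with the NuGEN Ovation Ultralow system and read for 76 cycles on an Illumina NextSeq. There were 2 control libraries (WT) and 2 knockout libraries (KO), and each sample's group and replicate number came from its label. The labels describe independent RNA samples from pools of cells and do not say whether each came from separate animals, so p-values here measure the spread between these samples, which may be in part technical.

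The deposited table holds raw read counts per gene symbol, whole numbers for 24421 genes with no row of unassigned reads. Per the submitters' processing notes, the tools named are TopHat2 2.1.1, SAMtools 1.5, Picard 2.9.4 and HTSeq 0.8.0, and the genome build is mm10. The gene annotation, the strand setting of the counting and the handling of duplicate reads are not given in the sources used here. Without strand, reads of a gene and of its antisense or overlapping partner cannot be told apart. Values of near-identical copies are uncertain as well, and these include Tpsb2, Cma1 and the other mast cell protease genes, Chil3, the histone genes and the major histocompatibility genes. Library totals were 29863594 counts in WT replicate 1, 25813391 in WT replicate 2, 22000036 in KO replicate 1 and 17787425 in KO replicate 2. A floor of 3 counts corresponds to between 0.100 and 0.169 CPM (reads per gene scaled to library size, the usual counts-per-million unit), and covers counting error only. Symbols were matched to the GENCODE annotation of the same build for positions, gene classes, lengths and GC content, with 23641 matched directly, 684 through a synonym and 96 unmatched.

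Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. TMM factors were used, genes were filtered with filterByExpr (minimum count 10, minimum total count 15), and KO was compared with WT in the quasi-likelihood test with no further covariate. Of the genes in the table, 14140 were tested, and 6762 had no read in any library. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are KO over WT on the log2 scale, and expression is given as CPM of TMM-scaled libraries, mean ± SD with n = 2 per group. The biological coefficient of variation was 0.266.

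The design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Gene lists covered processes of stem and progenitor cells and markers of other cell types that the sort could hold. The 35 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted together. Each list was also tested with an estimated correlation and with fry, which asks whether the genes of a list move one way and does not compare them with other genes (limma 3.58.1). The genes named are Zfp521, its paralog Zfp423 and its partner Ebf1, then the 12 genes with the largest fold change in each direction among those past the threshold, with a mean of at least 2 CPM and no overlap between the groups. Predicted gene models, pseudogenes, Y-linked genes and Xist were left out of that ranking. For the process lists the rule takes up to 4 members with the smallest p. Other genes, which include all named members of the cell type lists, were chosen after their values were seen. A few genes that the rule or the lists take are not reported here by name. For each list the count of genes past the threshold is also given adjusted over the list alone.

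On counts simulated for these libraries, with 13856 genes tested, the edgeR step recovered 45 of 100 genes changed 2-fold and 80 of 100 changed 4-fold, with 7 false calls, 5.19% of its calls. A simulated shift of -0.8 in 1 list was called by camera with the preset correlation (adjusted p = 2.1e-17), and not with an estimated correlation (adjusted p = 0.610) or by fry (adjusted p = 0.164). None of the 34 other lists was called by any of these tests. The estimated correlation and fry thus missed a known shift, so a list they do not call may still have moved. Genes were simulated independently of one another. In the data the estimated correlation was 0.77 for immediate early genes, 0.27 for the B lineage list and -0.03 for cell cycle genes. The simulation therefore does not show how often the preset correlation calls a list of correlated genes falsely. For dendritic cell markers the estimate was -0.06. It lay below the preset of 0.01 for the cell cycle and dendritic cell lists, so a higher correlation did not undo those calls. The alternatives were DESeq2's size factors and upper quartile factors in edgeR, no filter, a filter of at least 2 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, and leaving out each library in turn ("without either WT library" means with one or the other left out, never both). Chosen after seeing the data were fits without Rn45s, Lars2 and Xist, on protein-coding genes only, with trends of gene length and GC content removed, with the trend of fold change on expression level removed, and at equal depth by thinning.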

Results

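RNA sequencing of sorted LSK bone marrow cells gave raw read counts for 2 control (WT) and 2 Zfp521 knockout (KO) libraries, with totals from 17787425 to 29863594 counts. Between 15792 and 16142 genes had at least 1 read per library. Rn45s, the ribosomal RNA precursor, took 15.3% of counts in WT replicate 1, 15.7% in WT replicate 2, 14.6% in KO replicate 1 and 9.37% in KO replicate 2. Replicates ranked genes alike, with a Spearman correlation across genes of 0.985 between the WT libraries and 0.974 between the KO libraries; genes are not independent replicates. Their counts differed by far more than sampling noise, with a chi-square per gene of 39.5 for the WT pair and 54.3 for the KO pair. These values cover all genes with at least 20 counts in the pair, including Rn45s and the Xist gene described below. A few such transcripts can weigh heavily in them. The first principal component held 59.3% of the variance and separated KO from WT. Xist, the RNA of the inactive X chromosome, had 606 counts in WT replicate 2 and 160613, 227405 and 230977 in WT replicate 1, KO replicate 1 and KO replicate 2. The 4 Y-linked genes listed had 5606 counts in WT replicate 2 and 14, 9 and 12 counts in the others, so the WT group mixed a library with a male pattern and one with a female pattern.

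Zfp521 itself was lower in both KO libraries. Its counts were 1561 and 1429 in WT and 308 and 215 in KO, or 56.8 ± 1.03 CPM against 12.4 ± 2.12 CPM (SD, n = 2 each). The log2 fold change was -2.19 (SE 0.23, edgeR quasi-likelihood test, adjusted p = 0.000491), a 4.57-fold lower level. Zfp521 (ENSMUSG00000024420.9 in GENCODE) is a protein-coding gene with 8 annotated exons on the minus strand of chromosome 18, from 13687013 to 13972787 in mm10. The counts cover the whole gene, so they do not show which exons the remaining KO reads came from. Its paralog Zfp423 had 7 and 7 counts in WT and 3 and 8 in KO, too few to be tested. Ebf1, a transcription factor of early B cells and a known partner of Zfp521, fell from 80.7 ± 21.9 to 12.2 ± 6.23 CPM (log2 fold change -2.72, SE 0.33, adjusted p = 0.00110).

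The comparison of KO with WT asked which transcripts of the LSK fraction differ between the genotypes. In KO, 12 of 20 B lineage genes and 25 of 35 cell cycle genes were lower, and 7 of 12 dendritic cell and 6 of 11 mast cell markers were higher. Camera called these 4 lists, but none with an estimated correlation (adjusted p = 0.362, 0.121, 0.121 and 0.362). With an estimated correlation camera also missed a simulated shift, so a miss does not show that a list was unchanged. Of 14140 genes tested, 533 were higher and 425 lower in KO at an adjusted p under 0.05 (edgeR quasi-likelihood test), and both KO libraries lay on the same side of both WT libraries for all 958. The higher genes had the larger changes, with 411 of them over 2-fold against 149 of the lower genes. Of the higher genes 457 were protein coding, and of the lower genes 423. The counts depended on the libraries, with 160 higher and 95 lower without WT replicate 1, 220 and 101 without WT replicate 2, and 997 and 1161 without KO replicate 1. Of the calls 55.6% were higher, against 46.2% without KO replicate 1 and 69.7% with upper quartile factors, which moved the median of all genes from 0.02 to 0.10.

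**Figure D1:**
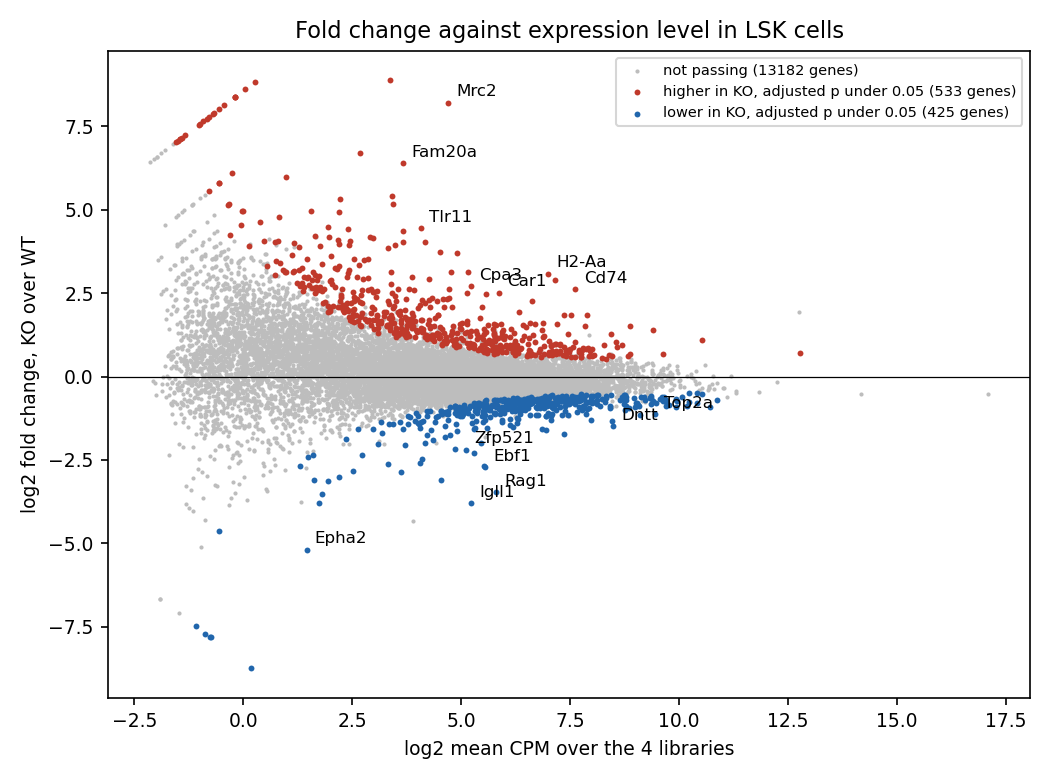
Each point is a tested gene, with the log2 of its mean CPM over the 4 libraries on the x axis and its log2 fold change (KO over WT) on the y axis; red points are the 533 genes higher and blue points the 425 genes lower in KO. Red points reach larger fold changes than blue ones, and most of those large changes are at low expression.

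Among the genes ranked by the naming rule, with a mean of at least 2 CPM, the largest increase was that of Mrc2, an endocytic collagen receptor. Mrc2 was at 0.168 ± 0.067 CPM in WT and 52.0 ± 1.01 CPM in KO (log2 fold change 8.21, SE 0.39, adjusted p = 1.6e-06). It was followed by Trnp1 (6.71), Fam20a (6.41), the mast cell chymase Cma1 (5.43), Tbc1d9 (5.32), Nsun7 (4.97), the C-type lectin Clec1a (4.92), the serotonin transporter Slc6a4 (4.49), the pattern recognition receptor Tlr11 (4.44), the Wnt receptor Fzd2 (4.44), Sept3 (4.35) and the lipid transporter Abca8b (4.21). Tlr11 rose from 1.47 ± 0.145 to 32.0 ± 1.42 CPM and Fam20a from 0.295 ± 0.265 to 24.9 ± 2.96 CPM. Most of these genes were close to the count floor in WT, so their exact folds rest on few WT reads. Abca8b missed the threshold without WT replicate 2 (adjusted p = 0.053), and Fzd2 in DESeq2 (adjusted p = 0.24).

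Among the 12 genes with the largest decrease under the same rule were 5 members of the B lineage list: Igll1 (-3.79) and Vpreb1 (-2.87), which form the surrogate light chain, the recombinase gene Rag1 (-3.46), the adaptor Blnk (-3.10) and Ebf1 (-2.72). Rag1 fell from 101 ± 2.03 to 9.22 ± 1.47 CPM and Igll1 from 69.8 ± 20.9 to 5.03 ± 0.499 CPM. The others were the receptor tyrosine kinase Epha2 (-5.19), Tnfrsf19 (-3.51), the thiopurine methyltransferase Tpmt (-3.12), the alkaline phosphatase Alpl (-3.10), the BCL2 family member Bok (-3.0), the Notch target Hes1 (-2.82) and Myl10 (-2.67). Tnfrsf19, Tpmt, Alpl, Bok and Myl10 missed the threshold when either WT library was left out, as Epha2 and Hes1 did without WT replicate 2 and Myl10 also without KO replicate 2.

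Most genes of the B lineage list were lower in KO. Of 20 tested members of the list of B lineage and Ebf1 target genes, 12 were lower and none higher, with a median log2 fold change of -2.11; adjusted over the list alone, 15 were lower. Besides the genes above, Rag2 fell from 80.0 ± 7.12 to 12.5 ± 0.829 CPM (-2.67), and Lef1, a transcription factor of lymphoid progenitors, from 28.6 ± 3.41 to 4.77 ± 0.224 CPM (-2.58). The B cell genes Cd79a (-2.18) and Pax5 (-2.05) were also lower, although Pax5 missed the threshold without WT replicate 2 (adjusted p = 0.088). Between 11 and 15 members were lower when each library was left out. The list was called by camera (adjusted p = 5.3e-30), but not with an estimated correlation (adjusted p = 0.362) or by fry (adjusted p = 0.137).

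The list of multipotent progenitor and lymphoid priming genes split. Rag1, Rag2, the terminal transferase Dntt (-1.48), Cnn3 (-1.22) and the interleukin receptor chain Il7r (-1.06) were lower, 2 members, among them Btla (2.1), were higher, and 15 of 22 members did not pass; Rag1 and Rag2 also belong to the B lineage list. Dntt fell from 528 ± 76.5 to 189 ± 38.4 CPM, while the cytokine receptor gene Flt3 was at 437 ± 27.3 CPM in WT and 576 ± 43.5 CPM in KO (log2 fold change 0.40, adjusted p = 0.104). The median was -0.21, and camera called the list lower (adjusted p = 0.00104; adjusted p = 0.548 with an estimated correlation), with 3 higher and 6 lower adjusted over the list alone. The lower members numbered 4, 3, 7 and 5 without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2. Cnn3 missed the threshold without either WT library, and Il7r without WT replicate 2.

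Most cell cycle genes were lower in KO. Of 35 tested members 25 were lower and none higher, 31 adjusted over the list alone, with a median of -0.85. Top2a, the topoisomerase of dividing cells, fell from 963 ± 14.5 to 443 ± 43.2 CPM (-1.12), and the mitotic genes Ccnb2 (-1.28), Bub1b (-1.14) and Tpx2 (-1.18) fell by similar amounts. Camera gave an adjusted p of 6.1e-28 (adjusted p = 0.121 with an estimated correlation), and fry also called this list (adjusted p = 0.0425), but no other process list that camera called. The count was 9 without WT replicate 1 and 10 without WT replicate 2, with medians of -0.81 and -0.91, 29 without KO replicate 1 and 23 without KO replicate 2.

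**Figure D2:**
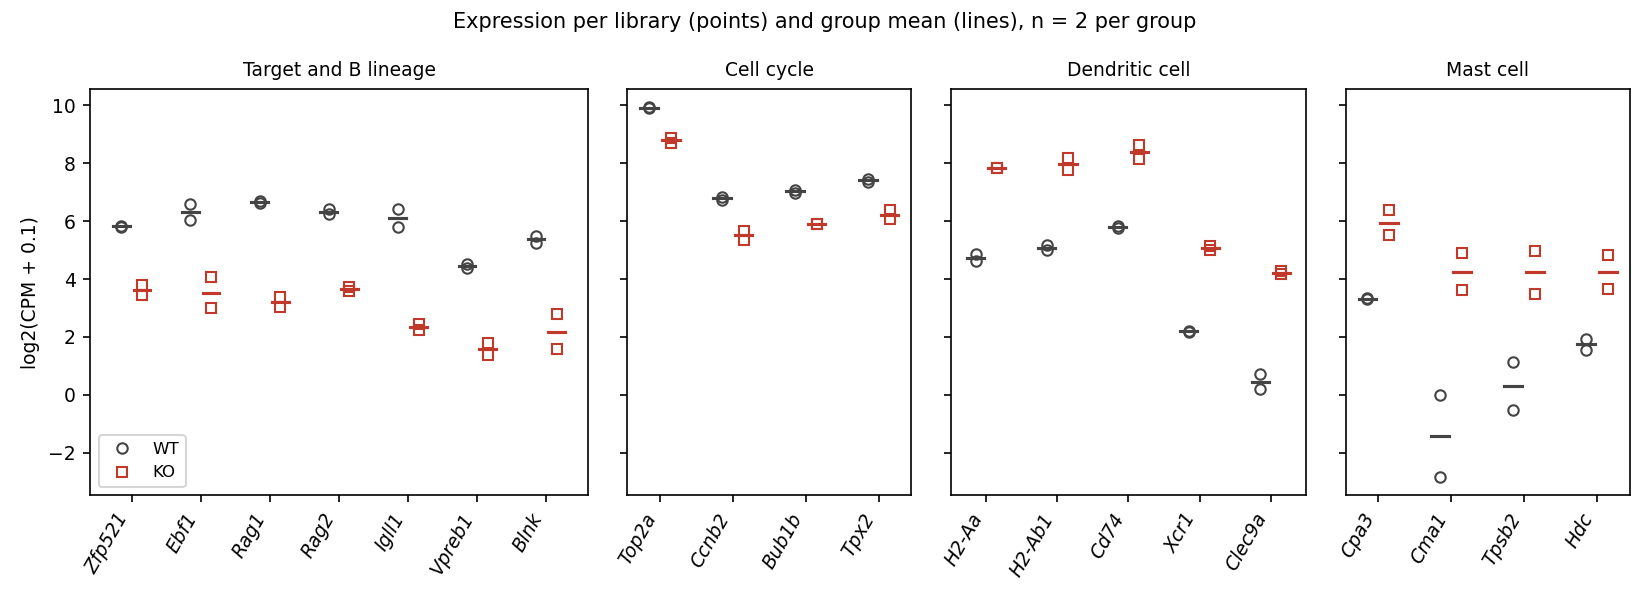
Points are single libraries (circles WT, squares KO) and lines are group means on the y axis, log2 of CPM plus 0.1; genes are grouped into the target and B lineage, the cell cycle, dendritic cells and mast cells. In each gene drawn both KO libraries lie on the same side of both WT libraries, below them in the first and second panels and above them in the other two.

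Some genes in lists of growth and metabolism were lower in KO. Of 14 heat shock and chaperone genes 6 were lower (median -0.64), among them Hsph1 (-1.60) and Hsp90aa1 (-0.86), and 11 were lower adjusted over the list alone. Of 36 oxidative phosphorylation genes, 35 had a negative fold change and 5 were lower, such as Atp5b (-0.76; list median -0.40), with 13 adjusted over the list alone. Of 24 Myc target and ribosome biogenesis genes, Npm1 (-0.71), Odc1 (-0.72) and Dkc1 (-0.69) were lower (median -0.44; 6 adjusted over the list alone). Of 24 cholesterol synthesis genes 2 were lower, among them Idi1 (-1.62), with the same count of 2 adjusted over the list alone (median -0.60). Camera gave adjusted p-values of 8.2e-07, 7.9e-08, 1.2e-05 and 1.5e-05 for these 4 lists, each with adjusted p = 0.548 with an estimated correlation. Without WT replicate 1 no member of the heat shock, oxidative phosphorylation or Myc list passed. Without KO replicate 1 the numbers were 9, 14, 12 and 7 in the order above; without WT replicate 2 they were 6, 1, 1 and 1, and without KO replicate 2 they were 6, 1, 3 and 3.

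Among 13 members of the NuRD corepressor complex, which Zfp521 is known to bind, Rbbp7 (-0.80), Hdac2 (-0.61) and Hdac1 (-0.67) were lower (median -0.29; camera adjusted p = 0.00525; adjusted p = 0.548 with an estimated correlation), with 5 lower adjusted over the list alone. None of them passed when either WT library was left out, 5 members passed without KO replicate 1, 2 without KO replicate 2, and the list missed the threshold with the trend on expression level removed (adjusted p = 0.0751). Of 21 immediate early genes, Dusp1 (-0.91) and Jun (-1.09) were lower, as they were adjusted over the list alone (median -0.66; camera adjusted p = 0.00264; adjusted p = 0.651 with an estimated correlation). The immediate early list missed the threshold without WT replicate 2 and without KO replicate 1, where its median was -0.14 and -0.22. The median was -0.82 without WT replicate 1 and -1.16 without KO replicate 2, so the size of the fall depended on single libraries. Of 25 glycolysis and hypoxia genes, Pkm (-0.94) and Gapdh (-0.65) were lower, with the same count of 2 adjusted over the list alone (median -0.35; camera adjusted p = 0.0226; adjusted p = 0.548 with an estimated correlation); no member passed without either WT library, 6 were lower without KO replicate 1 and 1, Pkm, without KO replicate 2. No member passed, over all genes or over the list alone, among 23 unfolded protein response genes (median -0.34; camera adjusted p = 0.0226; adjusted p = 0.602 with an estimated correlation) or among 40 cytosolic ribosomal protein genes (median -0.14; camera adjusted p = 0.0268; adjusted p = 0.692 with an estimated correlation). Without KO replicate 1, 7 members of each of these lists were lower, and 1 unfolded protein response gene was lower without WT replicate 2 and without KO replicate 2. The glycolysis, unfolded protein response and ribosomal protein lists each missed the threshold without WT replicate 1 and without KO replicate 2 (adjusted p from 0.0664 to 0.360) and with the trend on expression level removed, where the adjusted p was 0.0751, 0.0984 and 0.780 and the ribosomal protein median was 0.03. The ribosomal protein list also missed it with the stricter filter (adjusted p = 0.0845), with protein-coding genes only (adjusted p = 0.0549) and with length and GC trends removed (adjusted p = 0.221).

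Of 24 genes of megakaryocyte and erythroid priming, 7 were higher in KO and none lower, 10 adjusted over the list alone, with a median of 0.80. They included the integrin gene Itga2b, at 6.30 ± 2.20 CPM in WT and 26.0 ± 0.528 CPM in KO (2.05), the carbonic anhydrase Car1 (2.52), Ermap (1.59) and Mfsd2b (1.71). Camera gave an adjusted p of 7.3e-07 (adjusted p = 0.548 with an estimated correlation and 0.198 by fry); 2, 5, 7 and 8 members passed without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2, with Ermap and Mfsd2b among those lost in the first case. Among 21 granulocyte and monocyte primed genes the protease gene Ctsg (2.1) and the transcription factor gene Irf8 (1.12) were higher and the myeloperoxidase gene Mpo (-0.63) was lower, with a median of 0.68 and 9 higher and 2 lower adjusted over the list alone. Camera called that list (adjusted p = 0.0125; adjusted p = 0.548 with an estimated correlation), but not without WT replicate 2 (adjusted p = 0.0570) or KO replicate 1 (adjusted p = 0.158). Its higher members numbered 1 without WT replicate 1, 2 without WT replicate 2, and 4 without either KO library. Irf8 and Mpo each missed the threshold without either WT library.

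Of 32 interferon response genes, Iigp1 (1.53) was the one higher member past the threshold, also when adjusted over the list alone, and it missed it without either WT library. The median was 0.62 (camera adjusted p = 0.00893; adjusted p = 0.673 with an estimated correlation). This rested on KO replicate 2: without it the median was -0.02 and the direction turned down (adjusted p = 0.738), and without KO replicate 1, 17 members were higher. Irf7, for example, was at 8.14 CPM in KO replicate 1 and 26.4 CPM in KO replicate 2, against 4.71 and 5.92 CPM in WT.

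Markers of other cell types were compared to describe the makeup of the sorted cells. Of 12 dendritic cell markers 7 were higher and none lower, 9 adjusted over the list alone (median 2.72). The major histocompatibility class II genes H2-Aa (3.08), H2-Ab1 (2.89) and H2-Eb1 (3.13) and the invariant chain Cd74 (2.61) were among them, with H2-Aa at 26.8 ± 3.27 CPM in WT and 227 ± 0.752 CPM in KO. Xcr1 (2.92) and Clec9a (3.85), receptors of a subset of conventional dendritic cells, rose as well, Xcr1 from 4.46 ± 0.044 to 33.7 ± 1.93 CPM. Camera gave an adjusted p of 1.3e-28 (adjusted p = 0.121 with an estimated correlation), and fry called the list (adjusted p = 0.0425). Of 11 mast cell and basophil markers 6 were higher, 8 adjusted over the list alone (median 2.62; camera adjusted p = 2.7e-10; adjusted p = 0.362 with an estimated correlation and 0.198 by fry). Cpa3, the mast cell carboxypeptidase, rose from 9.86 ± 0.122 to 64.6 ± 26.5 CPM (2.71), and Cma1, Tpsb2 (3.96), Hdc (2.62) and Mcpt4 (3.52) were higher too. With each library left out, 6 to 8 dendritic cell markers and 5 to 7 mast cell markers were higher. In the dendritic cell list 5 genes, and in the mast cell list 1 gene, belong to another list as well. In WT, 10 of the 12 tested dendritic cell markers and 4 of the 11 mast cell markers reached a mean of 2 CPM.

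Some neutrophil, monocyte and erythroblast markers were also higher in KO. All 13 neutrophil markers had a positive fold change and 7 passed, 11 adjusted over the list alone (median 0.92; camera adjusted p = 9.4e-10; adjusted p = 0.548 with an estimated correlation). Chil3 rose from 33.3 ± 5.90 to 128 ± 9.77 CPM (1.95) and S100a8 from 59.3 ± 13.5 to 140 ± 22.1 CPM (1.24). The neutrophil count was 1 without WT replicate 1, where S100a8 was among the genes lost, 5 without WT replicate 2, 4 without KO replicate 1 and 10 without KO replicate 2, and fry did not call the list (adjusted p = 0.198). Of 15 monocyte and macrophage markers, Fn1 (2.47), Ms4a6c (1.67) and Itgam (0.84) were higher, 5 adjusted over the list alone (median 0.84; camera adjusted p = 0.000106; adjusted p = 0.362 with an estimated correlation), and fry called the list (adjusted p = 0.0425). Without either WT library 1 member passed, without KO replicate 1, 4, and without KO replicate 2, 2. Of 8 erythroblast markers the transferrin receptor gene Tfrc (0.77) passed, and 5 adjusted over the list alone (median 1.01; camera adjusted p = 0.00310; adjusted p = 0.548 with an estimated correlation and 0.374 by fry). Tfrc passed only without KO replicate 2 when a library was left out, and the erythroblast list missed the threshold without WT replicate 1 (adjusted p = 0.0652) and without KO replicate 1 (adjusted p = 0.0790). Higher erythroblast members numbered 0, 3, 1 and 5 without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2, with medians of 0.54, 1.64, 0.53 and 1.13.

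**Figure D3:**
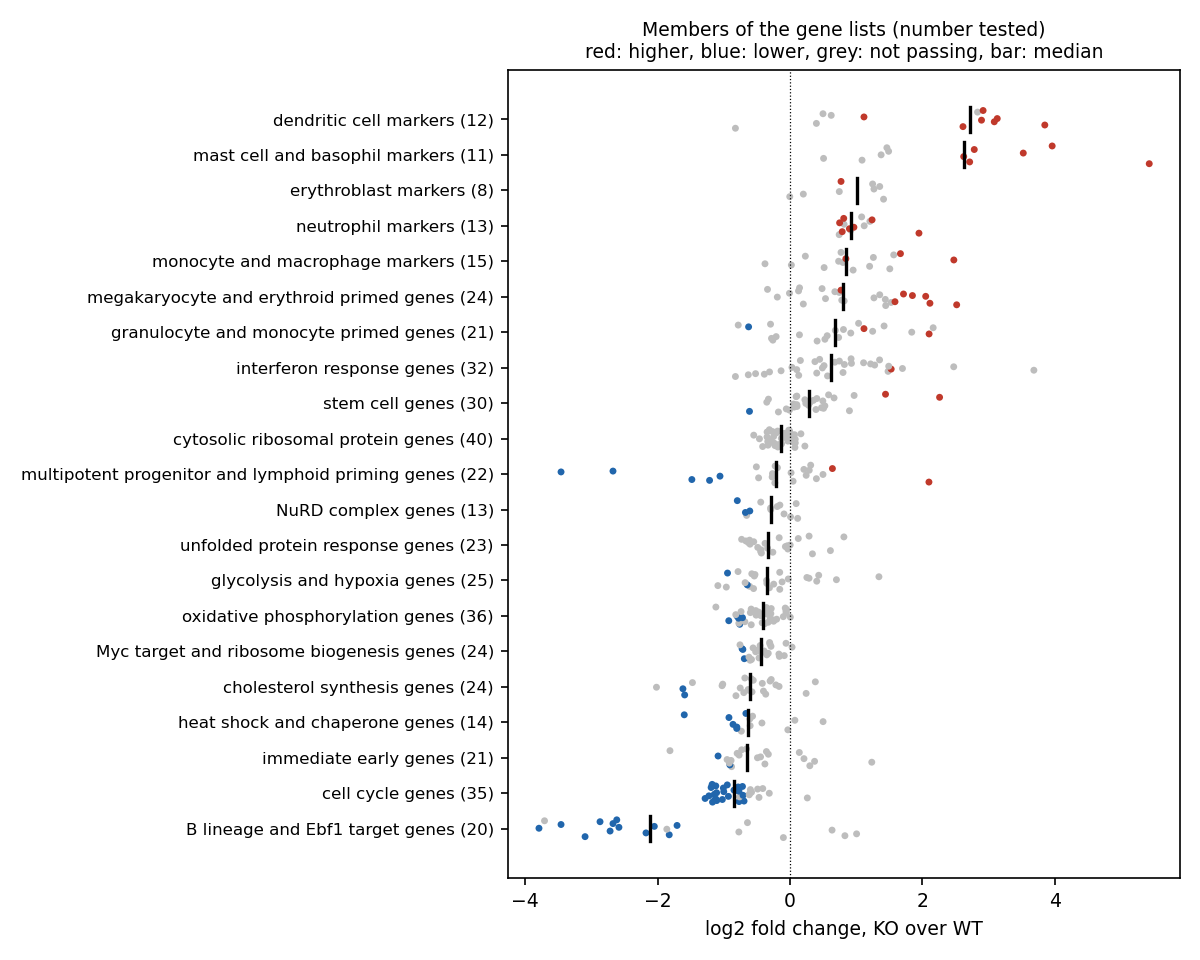
Each point is a tested member of a gene list, with its log2 fold change (KO over WT) on the x axis and the lists, with their number of tested genes, on the y axis; red is higher, blue lower and grey not past the threshold, and the bar is the list's median. Dendritic cell (2.72) and mast cell (2.62) markers have the highest medians and the B lineage list the lowest (-2.11).

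Stem cell genes did not pass as a list. Of 30 tested, Sult1a1 (2.26) and Vwf (1.44) were higher and Cd34 (-0.61) lower, the same counts as adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.0758). Sult1a1 missed the threshold without WT replicate 2, and Vwf and Cd34 missed it without either WT library and without KO replicate 2. The list was called with protein-coding genes only (adjusted p = 0.0412) and with the trend on expression level removed (adjusted p = 0.0194). The stem cell regulators Hlf (0.06, adjusted p = 0.848) and Mecom (0.10, adjusted p = 0.777) and the receptor genes Procr (0.22, adjusted p = 0.511) and Kit (0.08, adjusted p = 0.766) did not differ past the threshold.

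The other lists did not pass either. Camera adjusted p-values were 0.0604 for megakaryocyte and platelet markers, where Itga2b and F2rl2 were higher, 0.0907 for fetal stem cell genes, where Plagl1 and Igf2 were higher, and 0.147 for mature B cell markers, where 4 members, among them Ebf1, Cd79a and Pax5, were lower and Cd74 higher. They were 0.196 for p53 target and apoptosis genes (Pmaip1 higher, Cdkn1a lower), 0.233 for stromal and osteoblast markers (Pdgfrb higher), 0.403 for Notch and Wnt pathway genes (Lef1 and Hes1 lower), 0.439 for quiescence genes (Cdkn1a lower) and 0.525 for niche adhesion and homing receptors (Cdc42 lower). They were 0.714 for TGF-beta and BMP pathway genes (Id2 higher) and 0.959 for inflammatory and NF-kB genes (Birc3 higher, Cd69 and Tnf lower). Eosinophil (0.527), T and NK cell (0.533), plasma cell (0.564) and endothelial (0.959) markers had no member past the threshold. Adjusted over the list alone, higher and lower members numbered 2 and 0 for megakaryocyte and platelet markers, 3 and 1 for fetal stem cell genes, 2 and 5 for mature B cell markers, 1 and 2 for p53 targets, 3 and 1 for stromal markers, 0 and 2 for Notch and Wnt, 0 and 1 for quiescence, 1 and 0 for TGF-beta and BMP, 1 and 2 for inflammatory genes, 2 and 2 for T and NK cells and 1 and 2 for plasma cells, with none for the niche, eosinophil and endothelial lists. Of the members named, F2rl2, Igf2, Cdc42, Birc3 and Tnf missed the threshold without either WT library, Plagl1 without WT replicate 1, Pax5, Pmaip1, Cdkn1a, Hes1 and Cd69 without WT replicate 2, and Plagl1, Pmaip1, Cdc42 and Birc3 without KO replicate 2. Median and mean differed in sign for Notch and Wnt (0.02 and -0.15), TGF-beta and BMP (-0.05 and 0.08), plasma cell (0.21 and -0.19) and inflammatory genes (0.08 and -0.08). Mitochondrially encoded genes, Y-linked genes and Xist had too few tested members for a list test.

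A targeted allele can carry flanking DNA of another strain, so the genes around Zfp521 were compared with the rest of the genome. Within 5 Mb, 3 of 30 tested genes passed, against 6.76% of the genes elsewhere, an odds ratio of 1.53 (Fisher's exact test, two-sided, p = 0.454). They were Lama3 (2.41), Cabyr (1.53) and Colec12 (1.18), all higher in KO; Cabyr missed the threshold without either WT library, and Colec12 without either WT library and without KO replicate 2.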

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

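The test of noncoding genes that overlap no coding gene was chosen only after the result was seen. The 1457 genes of olfactory, vomeronasal and trace amine receptors, which blood progenitors are not known to use, had more reads in KO. Together they had 148 CPM in KO replicate 1 and 199 CPM in KO replicate 2, against 56.1 CPM in WT replicate 1 and 58.0 CPM in WT replicate 2. This was 3.04-fold more on average, and it was singled out because both KO libraries lay above both control libraries.

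Noncoding RNA genes were also higher in KO as a class: of 693 tested, 63 were higher and 1 lower, with a median log2 fold change of 0.84, against -0.01 for protein-coding genes. Xist was left out of this class. Among the libraries with a female pattern it was at 5378 CPM in WT replicate 1, 10337 in KO replicate 1 and 12985 in KO replicate 2, without TMM scaling. That comparison rests on a lone WT library. Neat1 rose from 103 ± 32.4 to 369 ± 114 CPM and Kcnq1ot1 from 245 ± 0.502 to 696 ± 140 CPM, the second with reads that overlapping genes on the other strand could share; the count of higher genes was 21 without WT replicate 1, 24 without WT replicate 2 and 105 without KO replicate 1. Reads spread evenly over the genome, such as genomic DNA, would have raised the receptor genes as much per kilobase. The median gain of 618 noncoding genes was 34.3 times that of the receptor genes in CPM per kilobase (95% bootstrap interval 27.0 to 38.8). These noncoding genes had passed the expression filter, while the receptor genes were pooled without filter or TMM scaling, so the ratio is not like for like. The interval leaves out the spread of the receptor gain. Bootstrap intervals here and below resample genes, so they treat genes as independent and carry no spread between libraries. A trend with expression level leaves a median difference of 0.50 (0.42 to 0.56) from protein-coding genes of like level. Intronic reads of overlapping coding genes leave a median of 0.82 (0.64 to 0.93) in the 285 noncoding genes that overlap no annotated coding gene. Each alone could thus account for part of the rise at most, and their joint share was not tested. Reads from coding genes nearby, outside their annotated bounds, were not examined. A difference in RNA quality or in the share of nuclear RNA, a library or sequencing batch, which is not given in the sources used here, and an effect of the knockout stay open and were not tested.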

How the results depend on the processing

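The fits without Rn45s, Lars2 and Xist, on protein-coding genes, with trends removed and at equal depth were chosen after seeing the data. Zfp521 was lower and past the threshold in all alternatives run, with log2 fold changes from -2.39 to -2.04. No gene that was called in the fit reported and again in an alternative changed direction. Genes that lost their call or were not tested in an alternative are not covered by this. Counts of higher and lower genes, 533 and 425 in the fit reported, were 1056 and 987 with no filter, 858 and 816 in DESeq2, and 443 and 262 with the trend on expression level removed; the cause was not tested. With a library left out they ranged from 160 to 997 higher and from 95 to 1161 lower, the lowest without WT replicate 1 (160 and 95) and WT replicate 2 (220 and 101), the highest without KO replicate 1 (997 and 1161); the lone library of a group is then assumed to vary like the others. With the replicate number as a block, 1312 were higher and 1314 lower; the correlation of same-numbered libraries' deviations was 0.08 over 2 pairs, and nothing in the labels pairs them. Higher genes were 69.7% of calls with upper quartile factors and 68.5% without WT replicate 2, 46.2% without KO replicate 1 and 49.96% with the replicate block, against 55.6%. Of the 3 process lists higher, 12 process lists lower and 5 cell type lists higher, 0, 0 and 0 were called with an estimated correlation (4 lists at an unadjusted p under 0.05) and 0, 1 and 2 by fry (8 lists). No cell type list was lower in the fit reported, 1 was with no filter, and 0 to 3 were with a library left out, 3 of them without WT replicate 1, 2 without KO replicate 2 and 1 without KO replicate 1. The odds ratio near Zfp521 was 1.84 within 2 Mb, 1.35 within 10 Mb, 2.06 at an unadjusted p under 0.05 and 1.34 with the replicate block, past the threshold in none. At an unadjusted p under 0.05, 12 of 30 genes within 5 Mb passed, against 24.5% elsewhere, close to the threshold (Fisher's exact test, p = 0.056). Of the 63 called genes among the 85 that the rule for named genes takes, 28 lost their call without WT replicate 1, 28 without WT replicate 2, 9 without KO replicate 2 and 2 without KO replicate 1; 13 lost it with the trend on expression level removed and 10 with upper quartile factors. With 2 libraries per group the samples split in 3 ways, so no share of splits was computed. Depth limited genes under about 0.169 CPM, the floor in the shallowest library.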

Other observations

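The families and windows below, and the tests of the LSK share, of one library's sex, of depth and of multipotent progenitors, were chosen only after the results were seen, and those of the LSK share and of multipotent progenitors were run on more than one set of genes, which did not all give the same outcome. Gene families defined by a shared symbol stem were tested for an excess of called genes (460 family and direction pairs, Fisher's exact test). Of 50 histone genes 11 were lower in KO (adjusted p = 9.5e-05), 10 of them in the cluster at 20 to 25 Mb of chromosome 13, the 1 window of 5 Mb among 1044 window and direction pairs with an excess of called genes (adjusted p = 0.0296). Replication-dependent histone genes are near-identical copies that lack poly(A) tails. Of 10 Mcm genes, which encode the replicative helicase and its partners, 5 were lower (adjusted p = 0.000817), and of 30 kinesin (Kif) genes, 6 (adjusted p = 0.0212). The counts were 2, 0 and 3 without WT replicate 1, 4, 0 and 2 without WT replicate 2, and 26, 7 and 7 without KO replicate 1.

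In the other direction 6 of 11 Abca lipid transporter genes were higher in KO (adjusted p = 0.000252), among them Abca8b and Abca9, which rose from 0.543 ± 0.654 to 8.68 ± 3.46 CPM (3.96); the count was 2 without either WT library and 3 without KO replicate 2. Of 12 Toll-like receptor genes 4 were higher, a share that missed the threshold (adjusted p = 0.0595): Tlr11, Tlr3 (2.60), Tlr9 (2.53) and Tlr13 (1.69). Tlr13 missed its own threshold without either WT library and without KO replicate 1. Of 16 olfactory receptor genes tested, 5 were higher (adjusted p = 0.0212), with 1 without WT replicate 1 and 2 without WT replicate 2 or KO replicate 2. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, rose from 2.13 ± 0.392 to 18.9 ± 2.0 CPM (3.15) and from 0.831 ± 0.094 to 14.97 ± 3.97 CPM (4.16), and both passed with each library left out.

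Dendritic cell and mast cell genes were higher in KO. A lower share of LSK cells stays open. If all other cell types took their place evenly, the markers of those types would rise alike. Only such an even rise was tested here, and an uneven one, of the types that pass the gates, was not. Among markers at 2 CPM or more in WT, the 72 of the 10 other cell types had a median of 0.63 (95% bootstrap interval 0.23 to 0.79). The 10 dendritic cell markers lay above it by 1.23 (-0.23 to 2.62) and the 4 mast cell markers by 1.42 (-0.13 to 2.39), too few markers to decide. Against all 97 tested markers of the other types, the 12 tested dendritic cell markers lay higher by 1.97 (-0.19 to 2.40). The 11 tested mast cell markers, most of them near the floor in WT, lay higher by 1.87 (0.61 to 2.78). The medians of the other types spread apart, but several rest on few markers, so they do not decide against an even rise. At 2 CPM or more in WT, medians were 0.91 (0.80 to 1.16) for neutrophil, 1.01 for erythroblast and 0.79 for monocyte and macrophage markers. They were 0.54 for megakaryocyte and platelet, 0.28 for stromal and osteoblast and 0.21 for plasma cell markers. Lower medians were -1.47 (-3.77 to -0.81) for eosinophil, -0.31 (-2.23 to 0.16) for endothelial and -0.15 for mature B cell markers. T and NK cell markers were at 0.05 (-0.78 to 1.27). The eosinophil, endothelial and T and NK cell values rest on 3, 6 and 4 markers, with none past the threshold. Over all tested markers the T and NK cell median was 0.94. The eosinophil median was 0.33 without KO replicate 1, and the endothelial median 0.61 without WT replicate 2. Mature cells held by the sort may contribute: 20 further dendritic cell markers, of which 13 reach 2 CPM in WT and 1 is in another list, had a median of 1.05 (0.59 to 2.06), with 8 higher (3 without either WT library), such as Ciita at 3.70 ± 0.003 and 16.6 ± 0.390 CPM and Cst3 at 134 ± 17.1 and 207 ± 16.8 CPM. In the same way 16 further mast cell markers, of which 8 reach 2 CPM in WT and 1 is in another list, had a median of 1.17 (0.60 to 2.96), with 5 higher (2 without either WT library), such as Slc18a2 at 52.0 ± 5.34 and 156 ± 53.9 CPM. Both medians cover all tested members, while the 0.63 for the other cell types covers only markers at 2 CPM or more in WT. Among the 13 dendritic cell markers at that level the middle value was Cst3 (0.62). Among the 8 mast cell markers the middle values were Gnaz (0.60) and Itgb7 (0.61). At that level the further markers lay no higher than the other cell types, so they cannot decide. Cst3 was at 0.75 without WT replicate 1 and 0.48 without WT replicate 2. The Kit and lineage gates should remove most dendritic cells but not mast cells, which carry Kit, and a change in gene use within LSK cells would give the same rise and stays open as a hypothesis.

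B lineage genes were lower in KO. Without WT replicate 2, the library with the male pattern, the median was -2.12 (-2.75 to -1.13, an interval over genes). The libraries left all had a female pattern, so sex does not account for the fall, though a lone WT library remains. At equal depth 12 genes of the list were still lower. CPM are already scaled to library size, so thinning was unlikely to undo such a fall and adds little. Fewer lymphoid-primed multipotent progenitors in the sort stay open: the 20 priming genes outside the B lineage list had a median of -0.087 (-0.27 to 0.27), but they went both ways, with Dntt, Cnn3 and Il7r lower and Btla higher. An effect of the knockout within the cells stays open as well and was not tested.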
